A study of Homo sapiens with 12 samples.

How the data were processed

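RNA sequencing of hTERT-RPE1 cells, a human retinal pigment epithelial line immortalised with telomerase, was reanalysed from the gene table of the series. Per the labels, 3 libraries came from untreated cells (control), 3 from cells treated with 0.5 µM reversine for 24 h, washed and harvested 48 h later, 3 from cells treated with 0.1 µM bafilomycin A1 (BafA1) for 6 h, and 3 from cells treated with 1 µM MG132 for 24 h. Per the labels' protocols, RNA was selected with oligo(dT), made into TruSeq libraries with inserts of 150 to 350 nt and sequenced as 50 nt reads on a HiSeq 2000. Samples were grouped by the treatment given in the labels. Replicate numbers follow the order of the sample records and pair nothing. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

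Reads were aligned with Bowtie 1.0.0 and quantified with RSEM 1.2.6 against hg19 (GRCh37), per the submitters' processing notes. The table held 53361 rows, one per Ensembl gene, with a symbol, transcript identifiers and a value for each of the 12 libraries, and its header named no unit. The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled to the mapped reads) because column totals differed between libraries, from 962891 to 2057717, which excludes TPM. Genes without reads held small positive values that depended on transcript length, as posterior mean estimates do, and an exact 0 marked transcripts shorter than a length that differed between libraries; 889 rows were 0 in every library. Read counts are unknown, so no counting interval can be given. From the floor of 3932 genes near the lowest value per length, depth relative to the deepest library ranged from 0.59 (BafA1 2) to 1 (control 3).

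The planned test assumed counts. Because the authors' table holds FPKM, the alternative written down with it was used: the limma trend method on log2(FPKM + 1), for rows with at least 1 FPKM in at least 3 libraries (30712 rows), in one fit of the 4 groups with no covariate (limma 3.58.1 in R 4.3.3). Residual degrees of freedom were 8 and the prior added 1.26. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05 in each of 6 comparisons. No scaling between libraries was added to the deposited FPKM. Adding 1 makes log2 differences of genes with low values smaller than the ratio of their means.

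A total of 31 gene lists, fixed before the data were examined, were tested with limma's camera, which compares a list with the other genes, with the correlation between genes preset to 0.01, lists of at least 5 tested members and Benjamini-Hochberg adjustment over lists within a comparison. As an alternative the correlation was estimated for each list. Members were also counted with p-values adjusted over the list alone. The lists were written for the comparisons against control and their tests between treatments were added after the values had been seen. Named genes followed a rule written before the data were examined. Against control it took the 6 highest and 6 lowest log2 differences among called genes with a mean of at least 2 FPKM and no overlap between the groups. It added up to 3 members of each list past its test, in the direction of the list, and at most 2 of other lists. These members were taken by smallest adjusted p, whether called or not. The rule also took 17 fixed genes. Between treatments the rule took the 3 highest, the 3 lowest and the fixed genes. Any other gene named in the text was chosen after its values were seen. Some genes chosen by the rule are not reported here.

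Overlaps between comparisons against the same controls were set beside 50 simulations of unchanged groups and beside the overlap of independent lists. The 3 controls cannot be divided into parts of 2. Each comparison was refitted on the 10 divisions of its 6 libraries into groups of 3. The fit was tested on data simulated from the control means and each gene's fitted residual spread: in the comparison of reversine with control over 30712 genes, 6% of 67 genes changed by 1 on the log2 scale, 34.3% of those changed by 2 and 48.5% of those changed by 3 were called, and 0.013% of the unchanged genes. On the same kind of data camera called the shifted list and 0 of 30 others.

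Names, gene types, transcript lengths and GC content came from GENCODE v29 by gene or transcript identifier. That annotation uses GRCh38, so none of its coordinates were used; 9866 rows were not in it and 82.5% of the tested rows (25349) had a GC content and length. A symbol was shared by 6784 rows. Values of near-identical copies are uncertain, because reads that fit several genes are divided by estimation, and so are overlapping and antisense genes, because no strand setting is stated.

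Alternatives were log2(FPKM + 0.1), no filter on low values, at least 5 FPKM in 3 libraries, a correction of each library for its trend with GC content and length (a spline of 5 degrees of freedom), median-ratio scaling, a term for the 3 libraries with 9118 to 10150 rows at 0, transcripts of at least 400 nt, that filter with the term and the correction together, rows summed by symbol, 4 libraries with a falling GC trend left out, each library left out in turn, and only the 2 groups compared. The stricter filter in FPKM, the correction for GC content and length, the median-ratio scaling, the term for 3 libraries, the 400 nt filter, its combination with both, the sums by symbol and the omission of 4 libraries were chosen after the data had been seen. The others were planned. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.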

Results

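Gene expression was measured by RNA sequencing in 12 libraries from hTERT-RPE1 cells, 3 each from untreated cells and from cells exposed to reversine, bafilomycin A1 (BafA1) or MG132. The labels name no vehicle and no time for the controls, so differences from control include any effect of solvent or time in culture. Reversine inhibits the kinase Mps1, so that cells divide with missegregated chromosomes and become aneuploid. BafA1 inhibits the proton pump of lysosomes (the V-ATPase), which stops acidification and autophagic degradation, and MG132 inhibits the proteasome. Values are deposited FPKM, and 30712 genes were tested. Read counts are unknown. The depth of each library relative to the deepest, estimated from the floor of the values, was 0.79 to 1 in controls, 0.72 to 0.89 after reversine, 0.59 to 0.74 after BafA1 and 0.68 to 0.91 after MG132. Fold changes are log2 differences of FPKM + 1, which understate changes of genes with low values, and adjusted p-values come from limma for genes and from camera for gene lists.

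The libraries of a group were not alike in every technical respect. GC trends were taken relative to each gene's mean over the 12 libraries, so 0 marks the average library. On that scale values fell with transcript GC content in reversine 1, BafA1 3, MG132 2 and MG132 3. The slopes were −0.362, −0.095, −0.464 and −0.496 log2 units per 10 percentage points. They were above 0 in the other 8 libraries, with 0.084 in MG132 1. A falling GC trend is meant in this relative sense throughout, and BafA1 3 and MG132 1 lie close to the dividing line. In control 3, MG132 2 and MG132 3 the shortest transcript with a value above 0 was 174, 234 and 209 nt long, against 74 to 101 nt in the other libraries, and 9118 to 10150 genes were listed at 0. The 10 most abundant genes held 42.9% of the total FPKM in BafA1 2 and 9.3% to 23.2% in the other libraries. Mitochondrially encoded genes held 20.2% of the total in MG132 3 and 2.6% to 9% elsewhere. The median log2 difference of all tested genes from control was 0.093 after reversine, 0.141 after BafA1 and 0.039 after MG132.

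**Figure D1:**
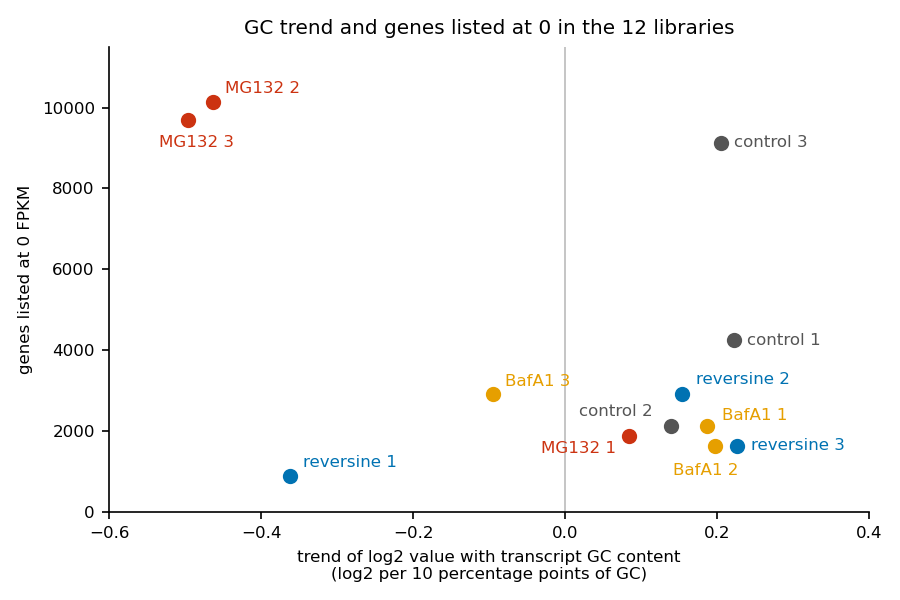
Each point is a library, coloured by treatment. The horizontal axis gives the trend of its log2 values with transcript GC content (log2 per 10 percentage points). That trend is relative to the mean of the 12 libraries. The vertical axis gives the number of genes listed at 0 FPKM. Reversine 1, BafA1 3, MG132 2 and MG132 3 lie left of 0, and control 3, MG132 2 and MG132 3 have 9118 to 10150 such genes.

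The comparison of reversine with control asked which genes differ in cells that had passed through faulty mitoses. After reversine, 642 genes were called, 246 higher and 396 lower, and 398 of them differed at least 2-fold (130 higher, 268 lower). Protein-coding genes made up 571 of the calls. All 3 libraries lay on one side of all 3 controls for 20.1% of the tested genes. Chance gives 10% only if the libraries are alike in depth and preparation. The count was 246 without control 1, 332 without control 2, 253 without control 3 and 305 without reversine 2. Without the 4 libraries with a falling GC trend it was 859. Under median-ratio scaling 394 genes were higher and 336 lower. The GC and length correction gave 1296 genes, and with the batch term and longer transcripts as well 2366. A fit of reversine and control alone gave 22 genes (14 higher, 8 lower) and lost 44 of the 52 calls of genes chosen by the naming rule, with limma adjusted p of 0.0532 to 0.274. Among those lost there are GABARAPL1, DDIT3, BTG2 and GDF15 (0.0555 each), CDKN1A (0.0855) and WIPI1 (0.0876), so these calls rest on a spread estimated from all 4 groups.

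Macroautophagy encloses cytoplasm in a membrane that carries lipid-bound LC3 and GABARAP proteins, and delivers it to lysosomes. Receptors such as p62, the product of SQSTM1, bind ubiquitinated cargo and are degraded with it. The transcription factors TFEB and TFE3 raise many genes of lysosomes and autophagy when lysosomal function is impaired, so these genes were grouped by function. Of 10 autophagy receptors, 2 rose after reversine, 0 fell and 8 did not pass (adjusted over the list alone, 5 rose), with a median log2 difference of 0.45. That list passed its test (camera adjusted p 0.000587, and 0.000141 to 0.034 over the alternatives). SQSTM1 (ENSG00000161011) rose from 376 ± 5.66 to 887 ± 195 FPKM (mean ± SD, n = 3; log2 difference 1.21, limma adjusted p 0.0134). That call was lost without control 1 (0.0642), control 2 (0.0608), control 3 (0.0666), reversine 2 (0.061) or reversine 3 (0.0577), in a range of 2.84e-05 to 0.0959 over the alternatives. The other called receptor, OPTN, was lost in the same 5 fits (limma adjusted p 0.109 to 0.177). Of 28 genes of the autophagy machinery, 3 rose, 0 fell and 25 did not pass (over the list alone, 4 rose and 1 fell). The machinery's median was 0.34 (camera adjusted p 0.0078, and 0.000381 to 0.12 over the alternatives, the highest with an estimated correlation). GABARAPL1 (ENSG00000139112) rose from 19.5 ± 2.26 to 81.2 ± 14.4 FPKM (log2 difference 1.99, limma adjusted p 0.000628). WIPI1 rose by 1.25 (limma adjusted p 0.00331) and MAP1LC3B by 1.05 (0.0101). The MAP1LC3B call was lost without control 1 (0.0586), without control 3 (0.0627) and without the 4 libraries with a falling GC trend (0.0549), in a range of 0.0058 to 0.12.

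Among lysosomal genes, 6 of 40 hydrolases and lumenal proteins rose, 0 fell and 34 did not pass (over the list alone, 10 rose and 1 fell). Their median was 0.28 (camera adjusted p 0.00096, and 2.45e-08 to 0.433 over the alternatives, the highest with an estimated correlation). ASAH1, which encodes acid ceramidase, rose from 28.7 ± 1.34 to 67.3 ± 6.39 FPKM (limma adjusted p 0.00205). Of 16 V-ATPase subunits, 1 rose, 0 fell and 15 did not pass (3 over the list alone). Their median was 0.47 (camera adjusted p 0.00145, and 2.08e-06 to 0.0513 over the alternatives, the highest with an estimated correlation). The call, ATP6AP2, was lost without control 1, 2 or 3 and without reversine 2 (limma adjusted p 0.0501 to 0.0707). None of 15 lysosomal membrane proteins was called and 1 rose over the list alone, with a median of 0.32 (camera adjusted p 0.026). That list was lost without control 2 (0.131), without reversine 2 (0.0647) and with an estimated correlation (0.0921), in a range of 0.000291 to 0.131. Of 9 MiT/TFE factors and feedback targets, GPNMB rose by 0.91 (limma adjusted p 0.00153) and the list, with a median of 0.11, did not pass (camera adjusted p 0.254; 0.0388 without control 3, in a range of 0.0388 to 0.696). TFEB, at 44.9 ± 41.6 FPKM in controls and 22.3 ± 10.0 after reversine, was at 92.9 in control 3 and 89.4 in MG132 2, above all other libraries, and was not called in any comparison. TFE3, LAMP1, CTSD and MCOLN1 were also not called after reversine, but without the 4 libraries with a falling GC trend LAMP1 (0.43, limma adjusted p 0.0389, in a range of 0.0389 to 0.977) and CTSD (0.55, 0.0248, in a range of 0.0248 to 1) passed as higher.

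Cells that missegregate chromosomes often stop dividing, with p53 and its target CDKN1A (p21) active and with secretion of inflammatory proteins. DNA replication genes are expressed in cycling cells through E2F, and mitotic genes through FOXM1. All of the 27 DNA replication genes had a difference below 0, with 16 lower, 0 higher and 11 that did not pass (21 lower over the list alone). Their median was −1.63 (camera adjusted p 3.87e-35; 2.83e-05 with an estimated correlation, the highest over the alternatives, down to 4.26e-50). MCM3 fell from 90.1 ± 0.549 to 24.5 ± 0.807 FPKM and RRM2 from 329 ± 19.6 to 65.3 ± 6.15 (log2 differences −1.84 and −2.32). Of 30 mitotic genes, 11 fell, 0 rose and 19 did not pass (16 fell over the list alone). Their median was −1.04 (camera adjusted p 2.63e-21, and 1.47e-33 to 0.0921 over the alternatives, the highest with an estimated correlation). CDC20 fell from 333 ± 10.7 to 56.4 ± 17.2 FPKM (log2 difference −2.59), AURKB by a log2 difference of −1.98 and CCNB2 of −1.90, while MKI67 was not called (−0.68). Without the 4 libraries with a falling GC trend MKI67 passed as lower (−1.19, limma adjusted p 0.0354, in a range of 0.0354 to 0.88). Other genes with the largest falls were ASF1B (−2.66), MYBL2 (−2.58) and UHRF1 (−2.55).

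Of 27 p53 targets, 6 rose, 0 fell and 21 did not pass (17 rose over the list alone). Their median was 0.90 (camera adjusted p 8.86e-15, and 3.42e-20 to 0.000657 over the alternatives). CDKN1A rose from 219 ± 31.9 to 966 ± 307 FPKM and BTG2 from 3.18 ± 0.071 to 17.3 ± 0.664 (log2 differences 2.09 and 2.13). TP53INP1 rose by 2.11, and MDM2 was not called (1.25, limma adjusted p 0.282). Of 18 NF-kB and secretory genes, 9 rose, 0 fell and 9 did not pass (14 rose over the list alone). Their median was 1.03 (camera adjusted p 1.84e-19, and 2.6e-24 to 0.000128 over the alternatives). IL8 (CXCL8) rose from 1.10 ± 0.204 to 22.6 ± 6.77 FPKM and IL1B from 18.4 ± 1.28 to 133 ± 16.1 (log2 differences 3.46 and 2.79). CCL2 rose by 1.60, CXCL2 by 1.49 and the chemokine gene CCL3 by 2.99.

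Stress lists moved less evenly. Of 27 ATF4 targets, 4 rose, 5 fell and 18 did not pass (7 and 9 over the list alone), with a median of −0.08, a mean of 0.05 and a camera test pointing down (adjusted p 0.601). DDIT3, which encodes CHOP, rose by 1.67, and GDF15 rose from 0.420 ± 0.131 to 10.6 ± 3.68 FPKM (log2 difference 2.97). PHGDH (−1.56), PSAT1 (−1.38) and ASNS (−1.09), genes of amino acid synthesis, fell; these 3 were picked after their values were seen. Heat shock targets (22 genes, 1 higher, 1 lower, list alone 1 and 2, median 0.11, adjusted p 0.78), ER chaperones (22 genes, 2 higher, list alone 2, 0.09, 0.78) and NRF2 targets (13 genes, 1 higher, list alone 3, 0.04, 0.83) did not pass camera. HSPB8 rose by 1.42, HMOX1 by 1.41 (from 34.0 ± 4.69 to 92.3 ± 16.8 FPKM), and DNAJB1 (0.35) and HSPA1A (0.17) were not called. HSPA8 fell (−0.64), a call lost without control 1 (0.0512) in a range of 0.00714 to 0.135.

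Of 32 proteasome subunits, 1 fell after reversine and 31 did not pass (2 fell over the list alone), with a median of −0.19 (camera adjusted p 2.86e-05, and 8.94e-09 to 0.187 over the alternatives, the highest with an estimated correlation). The call, PSMC3, was lost without control 1, 2 or 3 and without reversine 2 (limma adjusted p 0.0659 to 0.127). Of 23 HIF targets, 3 rose and 0 fell (11 rose over the list alone), with a median of 0.49 (6.45e-07, and 3.75e-09 to 0.0513 over the alternatives, the highest with an estimated correlation). ANGPTL4 rose by 2.46 and MXI1 by 1.08. Of 13 mitochondrially encoded genes, 10 rose (10 over the list alone), with a median of 0.93 (2.16e-14, and 2.23e-18 to 0.0513, the highest with an estimated correlation). Their share of the total was 9% in reversine 1, and 4.7% and 5.4% in reversine 2 and 3, within the 2.9% to 5.6% of the controls, and the median was 0.80 without the 4 libraries with a falling GC trend. Of 20 interferon-response genes, 2 rose and 1 fell (5 and 1 over the list alone; median 0.50, 5.48e-06, and 4.63e-07 to 0.0899, the highest with an estimated correlation), among them IFI6 (1.37). Of 12 immediate early genes, 4 rose (list alone 4 higher, 2 lower), with a median of 0.37 (0.00749; 0.0616 without control 2 and 0.406 with an estimated correlation, from 0.000236). EGR1 rose by 1.97 and FOSB by 0.93. Cytosolic ribosomal proteins (75 genes, 0 called, list alone 0, median −0.09; 0.00989) were lost without control 3 (0.154) and with an estimated correlation (0.687), in a range of 1.12e-05 to 0.853, and their median was 0.03 under median-ratio scaling. Nuclear-encoded respiratory chain genes (40 genes, 0 called, list alone 0, median −0.15; 0.0107) were lost without control 3 (0.122) and with an estimated correlation (0.436), from 4.94e-05.

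The other lists did not pass after reversine: cholesterol synthesis (24 genes, 1 higher, 1 lower, list alone 2 and 2, median 0.09, camera adjusted p 0.798), fatty acid synthesis (9 genes, median −0.11, 0.707), iron handling (8 genes, median 0.08, 0.481), metallothioneins (8 genes, median −0.15, 0.653) and extracellular matrix (23 genes, list alone 2 higher, 0.04, 0.601). The matrix list passed without reversine 1 (0.0323, in a range of 0.0194 to 0.982). Retinal pigment epithelium markers (9 genes, list alone 1 higher, 0.20, 0.102) passed without reversine 1 (0.0184, in a range of 0.0184 to 0.509). Markers of blood (7 genes, median 0.06, 0.821), other epithelia (8 genes, median 0.06, 0.534), neurons (6 genes, median 0.18, 0.16) and endothelium (5 genes, median 0.07, 0.75) had no member called. The comparison rests on a population of cells, so proportions of aneuploid or arrested cells were not measured.

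The comparison of BafA1 with control asked what a few hours without lysosomal acidification change. After BafA1, 81 genes were called, 62 higher and 19 lower, and 63 differed at least 2-fold (52 higher, 11 lower). Protein-coding genes made up 76 of them. The groups did not overlap for 23.1% of the tested genes, and 2187 genes had an unadjusted p under 0.05. The 10% that chance gives holds only for libraries alike in depth. All BafA1 libraries (0.59 to 0.74) were shallower than all controls (0.79 to 1), so genes near the floor can separate through depth. The count was 19 without control 1, 24 without control 2, 21 without control 3, 22 without BafA1 1, 27 without BafA1 2 and 34 without BafA1 3. It was 56 without the 4 libraries with a falling GC trend. With the GC and length correction 131 genes were higher and 86 lower, and with the batch term and longer transcripts as well 576 were called. A fit of BafA1 and control alone gave 24 genes and lost 12 of 23 calls of genes chosen by the naming rule (limma adjusted p 0.0595 to 0.161).

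Cholesterol taken up with LDL is released in lysosomes by acid lipase and leaves through the NPC proteins. When little of it reaches the endoplasmic reticulum, SREBP factors are processed and raise the genes of sterol synthesis and uptake. Of 24 cholesterol genes, 12 rose, 0 fell and 12 did not pass (23 rose over the list alone). Their median was 1.52 (camera adjusted p 6.56e-33, and 2.09e-42 to 0.000782 over the alternatives, the highest with an estimated correlation). INSIG1 (ENSG00000186480) rose from 51.7 ± 5.38 to 346.5 ± 18.6 FPKM (log2 difference 2.72, limma adjusted p 5.21e-05). HMGCS1 rose from 15.4 ± 2.12 to 121 ± 34.6 FPKM (2.86, limma adjusted p 0.00922). Its call was lost without control 1 (0.0696), control 3 (0.0516) or BafA1 1 (0.0504), in a range of 3.57e-05 to 0.0696. Of 9 fatty acid genes, 3 rose and 0 fell (8 rose over the list alone), with a median of 1.03 (camera adjusted p 7.87e-13, and 8.4e-19 to 0.00864, the highest with an estimated correlation). The calls of ACSS2 and FADS2 were lost without any 1 of the 6 libraries compared (limma adjusted p 0.051 to 0.117). SCD, the stearoyl-CoA desaturase, rose from 98.2 ± 2.58 to 647 ± 154 FPKM (log2 difference 2.68).

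HIF factors raise genes of glycolysis, pH control and mitochondrial removal when prolyl hydroxylases lack oxygen or iron. Of 23 HIF targets, 6 rose, 0 fell and 17 did not pass (20 rose over the list alone), and all 23 had a difference above 0. Their median was 1.23 (camera adjusted p 1.27e-30, and 1.89e-38 to 0.000922, the highest with an estimated correlation). CA9, which encodes a carbonic anhydrase, rose from 4.09 ± 0.708 to 51.4 ± 9.46 FPKM (log2 difference 3.36, limma adjusted p 0.00148). PFKFB4 rose by 2.40 and MXI1 by 2.00. DDIT4, listed with the ATF4 targets, rose by 2.37. None of 8 iron handling genes was called (list alone 0, median 0.09, mean −0.01, camera pointing down with adjusted p 0.432).

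Of 10 autophagy receptors, BNIP3L rose from 83.6 ± 8.92 to 167 ± 20.5 FPKM (log2 difference 0.99, limma adjusted p 0.0118) and the rest did not pass (1 over the list alone). That call was lost without control 1 (0.0584), control 2 (0.0595), control 3 (0.0759) or BafA1 1 (0.0567), in a range of 0.00371 to 0.137. The receptors' median was 0.14 (camera adjusted p 0.0721; 0.0246 without control 3 and 0.0264 without BafA1 2, up to 0.496). None of 28 genes of the autophagy machinery was called (list alone 2 higher, 0.24, 0.229), and SQSTM1 (0.35), MAP1LC3B (0.30), GABARAPL1 (0.75) and WIPI1 (0.91) did not pass. The WIPI1 result depended on the setting, with a limma adjusted p of 0.0581 that passed under 7 of 17 alternatives (0.00453 to 0.329). GABARAPL1 passed under 2 (0.0182 to 0.611) and SQSTM1 under 1, the GC and length correction (0.0227 to 0.975). Hydrolases (40 genes, 0 called, list alone 0, median 0.07, camera pointing down, adjusted p 0.829), lysosomal membrane proteins (15 genes, 0 called, list alone 1 higher, median 0.02, camera pointing down, 0.969) and MiT/TFE genes (9 genes, 0 called, list alone 1 higher, 0.37, 0.131) did not pass; the last passed without control 3 (0.00622, up to 0.579 over the alternatives). V-ATPase subunits (16 genes, 0 called, list alone 0) had a median of −0.11 (camera adjusted p 0.0236). That list was lost without BafA1 1 (0.0516), without BafA1 2 (0.0916) and with an estimated correlation (0.144), in a range of 0.000318 to 0.215.

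DNA replication genes shifted down without a call for any of the 27 members (7 lower over the list alone), with a median of −0.48 (camera adjusted p 1.59e-17, and 3.1e-22 to 0.000445, the highest with an estimated correlation). The 32 proteasome subunits also had 0 calls (list alone 0) and a median of −0.29 (2.86e-15, and 5.31e-23 to 0.0344, the highest with an estimated correlation). NRF2 targets (13 genes, 1 lower, list alone 3 lower, median −0.15) had an adjusted p of 0.000198 (9.24e-07 to 0.0951 over the alternatives). The lower call, TXNRD1, was lost without any 1 of the libraries compared (limma adjusted p 0.0941 to 0.27). HMOX1 was not called (−1.13, limma adjusted p 0.0557) but passed as lower under 7 of 17 alternatives (0.00578 to 0.303). Small shifts were lost with an estimated correlation in heat shock targets (22 genes, 0 called, list alone 0, median −0.10, 0.000595 against 0.286, from 1.13e-06), ER chaperones (22 genes, 0 called, list alone 1 higher, −0.17, 0.00126 against 0.144, in 1.91e-06 to 0.259) and respiratory chain genes (40 genes, 0 called, list alone 0, −0.12, 0.000198 against 0.286, from 2.71e-09). Ribosomal proteins (75 genes, 0 called, list alone 0) had a median of −0.05, which was 0.02 with the GC and length correction (camera adjusted p 0.000103; 0.0916 without BafA1 2 and 0.492 with an estimated correlation, in 4.27e-19 to 0.632). Metallothioneins (8 genes, 0 called, list alone 0, −0.19, 0.0306) were lost without control 3 (0.127), without BafA1 2 (0.0999) and with an estimated correlation (0.462), from 0.00117. Mitochondrially encoded genes (13 genes, 0 called, list alone 0, 0.20, 0.0142) were lost without control 1 (0.0815), control 2 (0.153) or BafA1 1 (0.301) and with an estimated correlation (0.492), in 5.54e-05 to 0.502.

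Lists that did not pass after BafA1 were ATF4 targets (27 genes, 2 higher, list alone 2 higher, 1 lower, median −0.04, mean 0.04, camera pointing down, adjusted p 0.299), p53 targets (27 genes, 1 higher, list alone 1 and 1, −0.06, 0.131) and interferon genes (20 genes, median 0.16, 0.131). Mitotic genes (30 genes, 0 called, list alone 0) had a median of 0.10 with camera pointing down (0.151; 0.000705 without BafA1 3, up to 0.976). NF-kB and secretory genes (18 genes, 1 lower, list alone 1) had a median of 0.07 and a mean of −0.01 (0.336). Extracellular matrix genes (23 genes, 1 lower, list alone 1, median 0.02, mean −0.08, 0.14) passed without BafA1 1 (0.0481, in a range of 0.00366 to 0.936). Immediate early genes (12 genes, list alone 1 higher, 2 lower, median 0.05, mean −0.03, 0.131), retinal pigment epithelium markers (0.18, 0.14) and markers of blood (0.12, 0.488), other epithelia (0.14, 0.222), neurons (0.34, 0.195) and endothelium (0.16, 0.323) had no call over all genes. SERPINB2 fell by a log2 difference of −2.44, and RRS1, a ribosome assembly gene, fell from 56.9 ± 3.03 to 19.3 ± 1.48 FPKM (−1.51). Protein levels and LC3 lipidation were not analysed here.

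The comparison of MG132 with control asked what a day of proteasome inhibition changes. After MG132, 4549 genes were called, 2192 higher and 2357 lower, and 2765 differed at least 2-fold (1168 higher, 1597 lower). Protein-coding genes made up 3752 of them. The groups did not overlap for 33.9% of the tested genes (chance gives 10% for libraries alike in depth and preparation). The count was 2427 without control 1, 2920 without control 2, 2662 without control 3, 2510 without MG132 2, 2538 without MG132 3 and 12980 without MG132 1, where both remaining treated libraries have a falling GC trend and many genes at 0. The count without the 4 libraries with a falling GC trend is not used here, because MG132 1 is then alone in its group. The balance turned under median-ratio scaling (3223 higher, 2402 lower) and with the GC and length correction (3315 higher, 2611 lower). A fit of MG132 and control alone gave 3082 genes and lost 14 of 85 calls of genes chosen by the naming rule (limma adjusted p 0.0522 to 0.198). The call with the largest rise, RPL41P1 (7.82), is a short pseudogene of a ribosomal protein; its limma adjusted p of 0.0422 became 0.117, 0.101 and 0.0837 without control 1, 2 and 3, and 0.147 and 0.142 without MG132 2 and 3, in a range of 0.0128 to 0.367.

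When proteins are not degraded, HSF1 raises chaperones, NRF1 raises proteasome subunits, and the unfolded protein response and ATF4 raise genes of folding and amino acid supply. Of 22 heat shock targets, 18 rose, 0 fell and 4 did not pass (19 rose over the list alone). Their median was 1.73 (camera adjusted p 2.52e-13, and 2.91e-18 to 0.0554, the highest with an estimated correlation). HSPB8 rose from 14.7 ± 1.11 to 297.6 ± 44.2 FPKM and DNAJB1 from 53.9 ± 2.92 to 412.5 ± 90.7 (log2 differences 4.24 and 2.89). HSPA6 rose by 5.09, and the several near-identical records of HSPA1A and HSPA1B, whose values are uncertain one by one, rose by 1.12 to 5.72. Of 32 proteasome subunits, 21 rose, 0 fell and 11 did not pass (25 higher and 1 lower over the list alone). Their median was 0.94 (1.94e-09, and 1.33e-15 to 0.0726, the highest with an estimated correlation). PSMC4 rose from 108.7 ± 7.74 to 311 ± 34.4 FPKM (log2 difference 1.51). Of 22 ER chaperone and degradation genes, 13 rose and 0 fell (15 over the list alone), with a median of 1.03 (3.6e-06, and 8.15e-10 to 0.0572, the highest with an estimated correlation). HSPA5 (BiP) rose from 169 ± 4.29 to 1477 ± 288 FPKM (3.10). Of 27 ATF4 targets, 15 rose, 6 fell and 6 did not pass (16 and 7 over the list alone), with a median of 0.77 (0.00674). That list was lost without MG132 1 (0.0847) and with an estimated correlation (0.14), from 2.44e-05. DDIT3 rose from 21.9 ± 1.86 to 387 ± 59.3 FPKM (4.08). Of 13 NRF2 targets, 9 rose and 1 fell (9 and 2 over the list alone), with a median of 0.70 (0.000536, and 5.2e-06 to 0.0588, the highest with an estimated correlation). HMOX1 rose from 34.0 ± 4.69 to 408 ± 71.2 FPKM (3.54).

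Blocked proteasomes leave ubiquitinated proteins to autophagy, and SQSTM1 is itself an NRF2 target. Of 28 genes of the autophagy machinery, 11 rose, 0 fell and 17 did not pass (15 higher and 2 lower over the list alone). Their median was 0.74 (camera adjusted p 0.000162, and 9.12e-08 to 0.0572, the highest with an estimated correlation). GABARAPL1 rose from 19.5 ± 2.26 to 364 ± 58.7 FPKM and MAP1LC3B from 40.9 ± 6.60 to 203 ± 33.0 (log2 differences 4.15 and 2.28). Of 10 receptors, 6 rose and 0 fell (7 over the list alone), with a median of 0.76 (0.000536, and 5.7e-06 to 0.0554, the highest with an estimated correlation). SQSTM1 rose from 376 ± 5.66 to 3505 ± 907 FPKM (log2 difference 3.19, limma adjusted p 2.2e-05). Of 16 V-ATPase subunits, 9 rose and 0 fell (9 higher and 1 lower over the list alone), with a median of 0.88 (0.00496; 0.0628 without MG132 1 and 0.065 with an estimated correlation, from 9.23e-06). Of 15 lysosomal membrane proteins, 4 rose (6 over the list alone), with a median of 0.56 (0.0373); NPC1 rose by 2.08. The membrane list was lost without control 2 (0.0577), without MG132 1 (0.205) and with an estimated correlation (0.111), from 0.000254. Of 40 hydrolases, 14 rose and 6 fell (15 and 8 over the list alone), and the list did not pass (0.10, 0.3); SCPEP1 rose by 2.54. CTSD was not called (−0.32). Without the 4 libraries with a falling GC trend, which leaves MG132 1 alone in its group, its difference was 0.47. With MG132 1 alone, no test of the hydrolase list is given for that fit. Of 9 MiT/TFE genes, 3 rose (4 over the list alone; 0.51, 0.169), among them RRAGC (1.56) and FNIP2 (1.14).

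**Figure D2:**
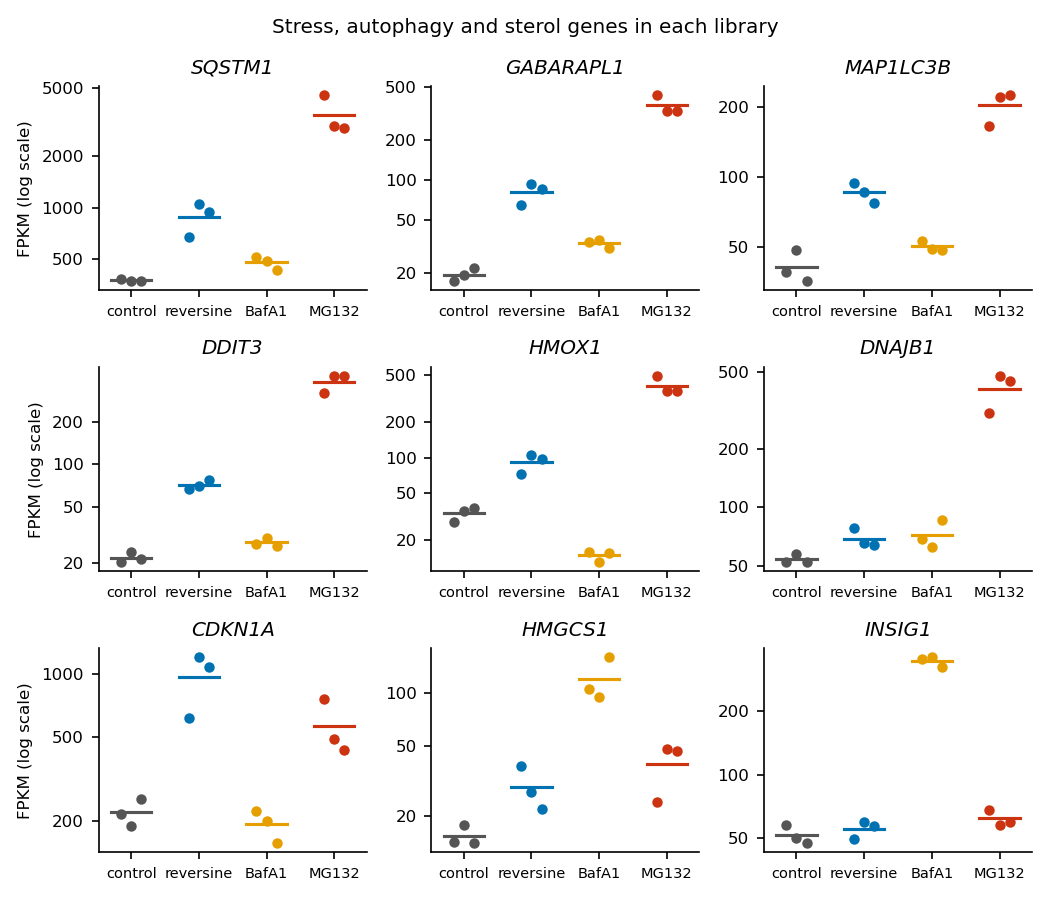
Each panel gives the FPKM of a gene on a log axis in the 12 libraries; points are libraries and lines are group means. SQSTM1, GABARAPL1, MAP1LC3B, DDIT3 and HMOX1 rose after reversine and more after MG132, DNAJB1 rose after MG132, and INSIG1 rose after BafA1.

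Proliferation genes fell after MG132 as well. Of 27 DNA replication genes, 19 fell, 0 rose and 8 did not pass (21 lower over the list alone), with a median of −1.50 (camera adjusted p 1.38e-16, and 5.76e-27 to 0.000493, the highest with an estimated correlation). MCM3 fell from 90.1 ± 0.549 to 11.2 ± 0.837 FPKM (log2 difference −2.90). Of 30 mitotic genes, 12 fell and 0 rose (12 over the list alone), with a median of −0.50 (2.28e-05, and 2.1e-19 to 0.457, the highest with an estimated correlation). PLK1 fell from 234 ± 18.8 to 33.0 ± 11.8 FPKM (−2.84). Of 27 p53 targets, 6 rose and 2 fell (10 and 2 over the list alone), and the list did not pass (0.59, 0.0908; 0.041 without control 3 and 0.0444 without MG132 3, in 0.000758 to 0.4). GADD45A rose by 1.76 and TP53I3 fell (−1.31). Of 18 NF-kB and secretory genes, 6 rose and 2 fell (8 and 2 over the list alone), and the list did not pass (0.37, 0.0609; 0.02 without control 3, 0.0248 without MG132 2 and 0.0444 without MG132 3, up to 0.275). Of 23 extracellular matrix genes, 2 rose and 8 fell (2 and 10 over the list alone), with a median of −0.39 (0.00709; 0.0787 without control 3, 0.0769 without MG132 1 and 0.41 with an estimated correlation, from 3.18e-05). THBS1 fell from 2123 ± 504 to 58.0 ± 38.6 FPKM and SPARC from 1603 ± 196 to 373.5 ± 53.2 (−5.32 and −2.10). After THBS1, the largest falls among protein-coding genes chosen by the naming rule were those of TGM2 (−4.76), PLAT (−4.46) and ID1 (−4.32).

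Of 9 fatty acid genes, 4 fell and 0 rose (4 over the list alone), with a median of −0.62 (camera adjusted p 0.000536, and 3.3e-06 to 0.111, the highest with an estimated correlation); FADS2 fell from 183 ± 10.9 to 36.6 ± 7.34 FPKM (−2.31). Of 24 cholesterol genes, 3 rose and 7 fell (4 and 7 over the list alone; −0.20, 0.15), and EBP fell (−2.13). Of 13 mitochondrially encoded genes, 8 rose (10 over the list alone), with a median of 0.67 (0.000201, and 1.07e-05 to 0.277, the highest with an estimated correlation). Their share of the total was 4.2% in MG132 1, within the 2.9% to 5.6% of the controls, and 7.9% and 20.2% in MG132 2 and 3. The median was 0.39 without the 4 libraries with a falling GC trend, which leaves MG132 1 alone. Lists that did not pass were HIF targets (23 genes, 4 higher, 6 lower, list alone 5 and 7, −0.17, 0.414), iron handling (8 genes, 3 higher, 1 lower, list alone 4 and 2, 0.54, 0.414), metallothioneins (8 genes, 1 lower, list alone 1, −0.16, 0.247) and immediate early genes (12 genes, 2 higher, 2 lower, list alone 3 and 2, 0.21, 0.226). FTL, a ferritin chain, rose from 634 ± 74.4 to 6590 ± 2092 FPKM (3.32). Interferon genes (20 genes, 1 higher, 3 lower, list alone 1 and 3, median 0.17), ribosomal proteins (75 genes, 3 lower, list alone 0, 0.24) and respiratory chain genes (40 genes, 2 higher, 6 lower, list alone 3 and 8, 0.12) had tests pointing down (0.953, 0.953 and 0.414). Retinal pigment epithelium markers (9 genes, 1 higher, 1 lower, list alone 3 and 1, 0.23, 0.461) and markers of blood (7 genes, list alone 3 higher, 0.25, 0.15), other epithelia (8 genes, 1 lower, list alone 4 and 1, 0.26, 0.258), neurons (6 genes, 1 higher, 1 lower, list alone 1 and 1, 0.11, 0.953) and endothelium (5 genes, median 0.19, 0.3) did not pass. MG132 1 differs from MG132 2 and MG132 3 in GC trend and in genes at 0, which widens the spread in this group.

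**Figure D3:**
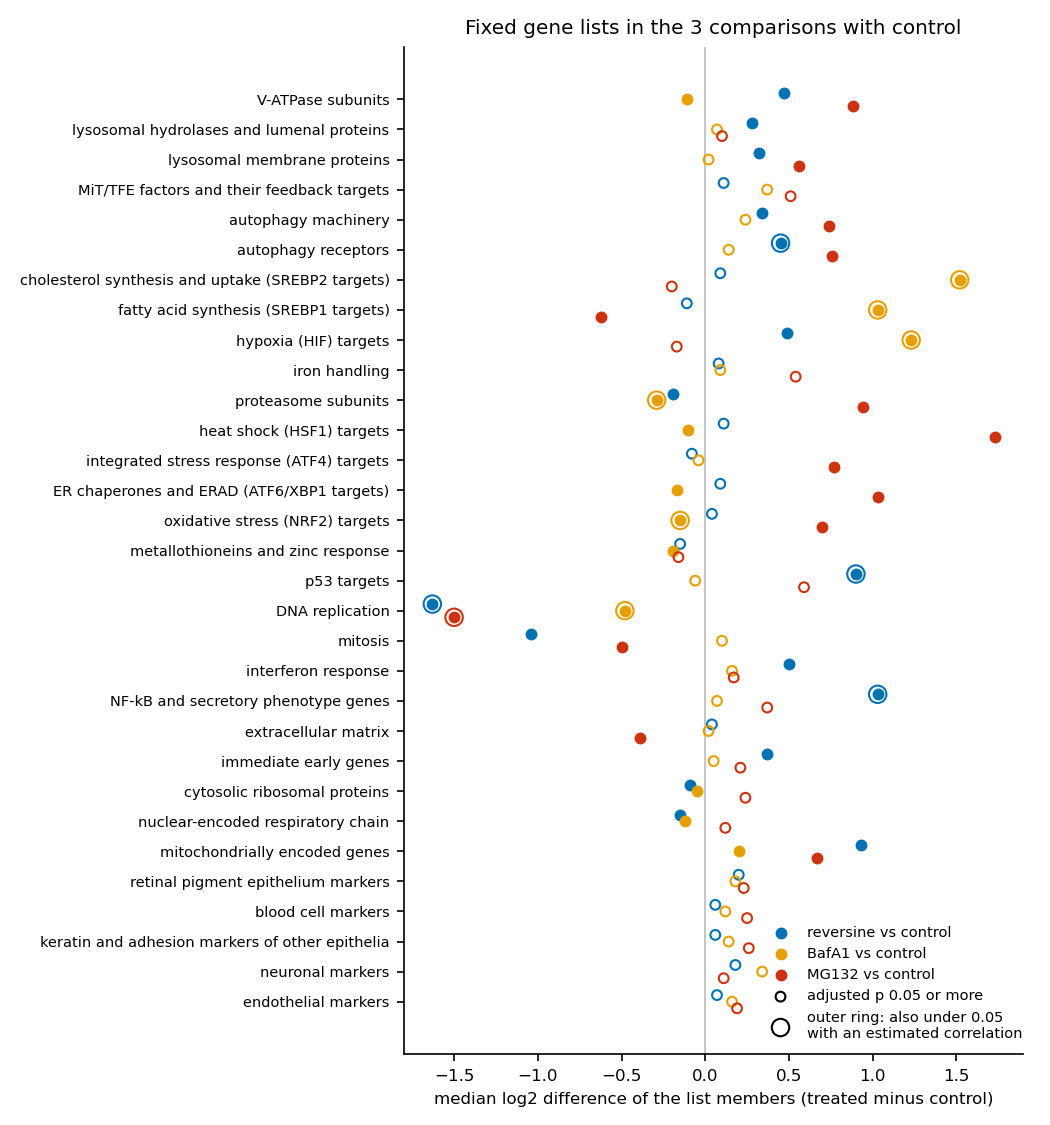
Each symbol is the median log2 difference of the tested members of a fixed gene list, treated minus control; filled symbols passed camera at an adjusted p under 0.05 and an outer ring marks those that also passed with an estimated correlation. DNA replication genes lie below 0 after all 3 treatments, NF-kB, mitochondrially encoded and p53 genes lie farthest right after reversine, sterol and HIF genes after BafA1, and heat shock genes after MG132.

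A further question was whether the treatments change genes in common. Reversine and BafA1 shared 17 calls in one direction (9 higher, 8 lower) and 3 in opposite directions; independent lists would share 0.5 higher and 0.2 lower. Simulated unchanged groups gave 0 for every pair, which sets no baseline for calls because unchanged groups have hardly any. Without control 1, 2 or 3 the shared calls numbered 4, 5 and 4; without reversine 1, 2 or 3 they numbered 35, 9 and 9; without BafA1 1, 2 or 3 they numbered 5, 6 and 6. Reversine and MG132 shared 482 (121 higher, 361 lower) and 28 in opposite directions, against 17.6 and 30.4 for independent lists; the shared calls numbered 183, 255 and 193 without control 1, 2 and 3, and 259 without reversine 2. BafA1 and MG132 shared 27 (17 higher, 10 lower) and 20 in opposite directions, against 4.4 and 1.5. Those 27 became 6, 6 and 7 without control 1, 2 and 3, 8, 9 and 11 without BafA1 1, 2 and 3, and 15 and 17 without MG132 2 and 3. Part of each overlap may come from the shared controls. The figures for independent lists treat all 30712 tested genes as equally likely to be called. Protein-coding genes, however, made up 76 of the 81 calls after BafA1 and 3752 of the 4549 after MG132. The figures are therefore likely too low, and none was computed for opposite directions. An excess over them alone does not show a common direction. Over all 30712 genes, correlations of the log2 differences across genes were 0.914, 0.052 and −0.148 for the 3 pairs in that order, against 0.499, 0.501 and 0.5 in simulation, and the covariance differed from the simulated one by 0.497, −0.4835 and −0.7256. A smaller set held 7249 genes with only transcripts of at least 400 nt and a mean of at least 5 FPKM. Over these the correlations were 0.642, 0.695 and 0.421, against 0.497, 0.5 and 0.499. The covariance differed by 0.097, 0.3742 and 0.1178. Transcript length and expression level both differ between the 2 sets and were not examined apart. For both pairs with MG132 the sign of that difference thus depends on the genes included, and genes are not independent replicates. The simulations drew each gene and library independently. The data hold structure that crosses treatments: deviations of reversine 1, BafA1 3 and MG132 2 and 3 within their groups correlated at 0.76 to 0.86. Over 8547 short genes control 3 had a median of −2.8 against control 1 and 2. The simulations therefore set no baseline for a common response. In 11 genes the call had the same direction after all 3 treatments: MXI1, BHLHE40, PBXIP1 and TP53INP1 rose, and NOP56, DKC1, LRRC59, STX11, TNFRSF11A, MARS2 and TMEM200B fell; apart from MXI1 and TP53INP1 they were picked from this overlap. The TP53INP1 call after BafA1 (limma adjusted p 0.0452) was lost under 13 of 17 alternatives, in a range of 0.00228 to 0.236. It was 0.132, 0.0995 and 0.225 without control 1, 2 and 3, and 0.236, 0.116 and 0.175 without BafA1 1, 2 and 3. The MXI1 call after reversine was lost without the 4 libraries with a falling GC trend (0.0502) and with only the 2 groups compared (0.143), from 0.000341.

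Direct comparisons asked where the treatments differ, and their list tests were added after the values had been seen. Exposure was 6 h for BafA1 and 24 h for MG132, and reversine cells were harvested 48 h after 24 h of drug. Differences between drugs therefore cannot be told apart from differences in time. Between reversine and BafA1, 377 genes were called, 136 higher after reversine and 241 lower, around a median of −0.143 over all genes. The count was 177 without reversine 2, 193 without reversine 3, 142 without BafA1 1, 189 without BafA1 2, 193 without BafA1 3 and 237 without the 4 libraries with a falling GC trend. Under median-ratio scaling 203 were higher and 212 lower. V-ATPase subunits were higher after reversine (median 0.49, camera adjusted p 3.4e-12, and 4.18e-15 to 0.000652 over the alternatives). p53 targets (0.99, 5.68e-34) and NF-kB genes (1.12, 5.85e-40) were higher, and DNA replication genes (−1.20, 7.62e-28), cholesterol genes (−1.31, 8.56e-39) and HIF targets (−0.81, 2.01e-14) were lower; these 5 lists passed under every alternative. GABARAPL1 was higher by 1.24 (limma adjusted p 0.00843), and SQSTM1 (0.87, 0.0908) and MAP1LC3B (0.76, 0.0641) did not pass. SQSTM1 passed without reversine 1 (0.0396), in a range of 0.000124 to 0.338, and MAP1LC3B ranged from 0.0412 to 0.35. HMOX1 (2.54), DDIT3 (1.33), CDKN1A (2.28) and SERPINB2 (3.74) were higher, and INSIG1 (−2.63) and CA9 (−2.22) were lower after reversine. A fit of these 2 groups alone gave 5 genes and lost 9 of 12 calls of genes chosen by the naming rule, among them HMOX1 (0.0582), CDKN1A (0.0961), DDIT3 (0.11) and GABARAPL1 (0.17).

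Between reversine and MG132, 2000 genes were called, 1082 higher and 918 lower after reversine. The count was 986 without reversine 2, 1044 without reversine 3, 935 without MG132 2, 966 without MG132 3 and 17052 without MG132 1. Proteasome subunits (median −1.14, camera adjusted p 6.72e-18), heat shock targets (−1.58, 2.11e-16), ER chaperones (−0.86, 2.86e-08), ATF4 targets (−0.60, 2.45e-05) and NRF2 targets (−0.85, 2.45e-05) were lower after reversine under every alternative. p53 targets were higher (0.54, 0.000525, and 1.68e-07 to 0.0372). Genes of the autophagy machinery were lower (−0.49, 0.000525; 0.0525 with an estimated correlation, from 1.06e-07), as were SQSTM1 (−1.98, limma adjusted p 0.000444) and GABARAPL1 (−2.15, 0.000127). PLAT (5.34), TGM2 (4.88) and THBS1 (4.25) were higher after reversine. A fit of these 2 groups alone gave 318 genes and lost 3 of 13 calls of genes chosen by the naming rule, among them THBS1 (0.052).

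Between BafA1 and MG132, 3334 genes were called, 1955 higher and 1379 lower after BafA1. The count was 1851 without BafA1 1, 2028 without BafA1 2, 1890 without MG132 2, 1900 without MG132 3 and 18401 without MG132 1. Cholesterol genes (median 1.65, camera adjusted p 7.4e-14), HIF targets (1.45, 4.87e-09) and DNA replication genes (1.16, 1.57e-09) were higher after BafA1, and proteasome subunits (−1.25, 4.41e-18), heat shock targets (−1.87, 6.53e-18), V-ATPase subunits (−0.90, 3.01e-05) and the autophagy machinery (−0.57, 4.24e-05) were lower, under every alternative. SQSTM1 (−2.84, limma adjusted p 4.23e-05), GABARAPL1 (−3.40, 6.92e-06), HMOX1 (−4.67) and HSPA6 (−5.19) were lower after BafA1. A fit of these 2 groups alone gave 1468 genes and lost 4 of 17 calls of genes chosen by the naming rule.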

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

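The tests of shared preparation, of GC content and of the response of reversine 1 were chosen only after the difference between libraries had been seen. Reversine 1, BafA1 3, MG132 2 and MG132 3 differ from the other libraries of their groups over many genes, and their differences resemble each other across treatments, with a lowest correlation of 0.76 over 6872 genes. The trend with GC content and transcript length that the correction captured was not the whole cause, because the lowest correlation was still 0.64 after it. The correction used means over the annotated transcripts of a gene and may leave part of such a trend. Whether GC content and length are the whole cause thus cannot be told. A weak or absent response of reversine 1 is argued against by a slope of 1.01 on reversine 2 and 3. The slope was taken over the 859 genes called without the 4 libraries. It was 0.06 to 0.264 in 50 simulations of a library without a response that share the controls and the selection of genes. The simulations drew each gene independently and left out the deviation that reversine 1 shares with the other 3 libraries. Their range may therefore be too narrow. A property of library preparation may explain the pattern, and a culture state shared by these libraries stays open.

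The tests on short transcripts were chosen only after the separation had been seen. Genes with short transcripts separate control 3, MG132 2 and MG132 3 from the other libraries: in control 3 their median difference from control 1 and 2 was −2.8 over 8547 genes, against 0.03 over 12577 long ones. A response to MG132 is argued against, because the median was 0.02 in MG132 1. The shortest fragment length assumed for each library when values were estimated may explain it, which can be settled only from the settings of that step. Of the 4549 genes called after MG132, 108 (2.4%) were short, though 8547 of the 30712 tested genes were. The pattern splits both groups and widens the spread of these genes, so few calls do not show that they were unaffected.

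The tests on histone genes were chosen only after their rise had been seen. Of 45 histone genes, 9 were called higher and 0 lower after reversine, with a median of 0.6 over all of them (camera p 8.37e-08, and 0.16 with an estimated correlation). Lower DNA replication genes as the whole cause are argued against, because the 45 genes had a median of −0.05 (SD 0.41) after MG132, where replication genes fell too. Whether RNA without a poly(A) tail was carried into the libraries cannot be told apart from a response: in BafA1 2 and MG132 2, which held more RN7SK than any reversine library, the joint median of the 45 genes was 0.58, but 1.03 in BafA1 2 and 0.03 in MG132 2. Against carry-over alone, MG132 1 had more RN7SK than reversine 3 (46.9 and 32.7 FPKM) but a median of −0.24 against 0.43. The 9 called genes were selected for their rise after reversine (1.60 to 1.68 in each library). No conclusion is therefore drawn from their lower values in BafA1 2 (0.68) and MG132 2 (−0.25). RN7SL2, another RNA without a poly(A) tail, was at 35.95 to 71.84 FPKM after reversine, within the 20.78 to 78.64 of the controls, and at 807.83 in BafA1 2. RN7SK and RN7SL2 thus disagree for the reversine libraries. The hypothesis that histone transcripts gain a poly(A) tail in cells leaving the cycle was not tested, and values of near-identical copies are uncertain.

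Each comparison was also fitted on the 10 divisions of its 6 libraries into groups of 3, which are too few for a share under 0.05. The real division gave 642 genes for reversine against control, 81 for BafA1 against control, 377 for reversine against BafA1 and 3334 for BafA1 against MG132, and 1 division (the real one) reached each count, with highest other counts of 0, 0, 257 and 0. For MG132 against control 2 divisions reached the real 4549, the other with 10598 genes, and that one follows the short-transcript libraries control 3, MG132 2 and MG132 3. With a term for those libraries 3934 genes were called. For reversine against MG132 2 divisions reached the real 2000. The other gave 3509 genes and follows the falling GC trend of reversine 1, MG132 2 and MG132 3. With the GC and length correction 2714 genes were called for the real division. The fit without the 4 libraries leaves MG132 1 alone, so its count is not used here. For reversine against BafA1 the division with 257 genes put reversine 1, reversine 3 and BafA1 2 together. Their shortest transcripts with a value above 0 were 74, 82 and 82 nt long. In reversine 2, BafA1 1 and BafA1 3 they were 92, 86 and 92 nt long. That division thus follows this length, and its cause was not tested. Divisions with many genes point to a structure of the samples.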

How the results depend on the processing

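Each result was refitted under alternatives, and the cause of a change was not tested. TMM or DESeq2 size factors, the DESeq2 test, scaling by library totals and rounding had been planned for counts and were not run, because the values are not counts. No paired analysis was possible because replicate numbers only follow the order of the sample records. Counting noise cannot be computed without read counts.

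With the GC and length correction 1296 genes were called for reversine (642 in the chosen fit), 217 for BafA1 (81) and 675 between reversine and BafA1 (377). Genes called in one direction rose from 17 to 93 for reversine and BafA1, from 482 to 959 for reversine and MG132, and from 27 to 96 for BafA1 and MG132. MLANA after MG132 turned from 0.38 to −0.09. With transcripts of at least 400 nt the counts were 1390, 252 and 704, the shared calls 111, 1043 and 120, and the lists after BafA1 4 in place of 13; 5 of the 31 lists had too few members left for a test. With these, the batch term and the correction together they were 2366, 576 and 1294, the shared calls 331, 1696 and 302, and the lists after BafA1 4. MLANA was then −0.06, and MCOLN1 between BafA1 and MG132 turned from 0.03 to −0.53. The batch term alone gave 984 genes between reversine and MG132 and 1932 between BafA1 and MG132.

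Shared calls of reversine and BafA1 numbered 31 with median-ratio scaling, 36 with a pseudocount of 0.1 and 28 with sums by symbol. Those of BafA1 and MG132 were 44 with a pseudocount of 0.1.

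Without the 4 libraries with a falling GC trend 2679 genes were called for MG132, 237 between reversine and BafA1, 1001 between reversine and MG132 and 1863 between BafA1 and MG132. CTSD after MG132 turned from −0.32 to 0.47. Between reversine and MG132 the median of ribosomal proteins turned from −0.30 to 0.23 and that of respiratory chain genes from −0.10 to 0.13.

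Fits of only the 2 groups compared gave 22 genes for reversine, 24 for BafA1, 5 between reversine and BafA1, 318 between reversine and MG132 and 1468 between BafA1 and MG132, with shared calls of 0, 11 and 6. With an estimated correlation 4 lists passed for reversine (16), 6 for BafA1 (13) and 1 for MG132 (14).

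Libraries were left out 1 at a time only within the groups compared. This gave 246 to 561 genes for reversine, 19 to 34 for BafA1 and 2427 to 12980 for MG132. It gave 142 to 299 genes between reversine and BafA1, and 935 to 17052 between reversine and MG132. Between BafA1 and MG132 it gave 1851 to 18401. Shared calls were 4 to 35 for reversine and BafA1, 183 to 647 for reversine and MG132 and 6 to 37 for BafA1 and MG132. Lists numbered 14 to 18, 11 to 14 and 10 to 16 for reversine, BafA1 and MG132.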

Other observations

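Ribosome biogenesis genes were chosen for a look only after their values had been seen. Of 30 such genes, 27 had a difference below 0 after BafA1, with a median of −0.38 and 3 called lower (NOP56, DKC1 and RRS1). The trend with GC content and length, as corrected here, is argued against as the cause. After the correction the median was −0.36 relative to protein-coding genes with a mean of at least 5 FPKM and only transcripts of at least 400 nt. The −0.38 before it had no such reference. Without the correction the median was also −0.37 after reversine, with 3 called lower, and −0.12 after MG132, with 9 called lower. No other explanation was tested.

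Chromosome-wide shifts were examined after reversine because the drug makes cells aneuploid. Gains or losses of the same chromosomes in most cells are argued against, since the largest median shift of an autosome in a reversine library was 0.15 after the GC and length correction, against up to 0.21 in an MG132 library. A mixture of cells with different karyotypes may be present and would leave such averages near 0.

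Among the comparisons with control, the list results that passed under every alternative were the autophagy receptors, p53, DNA replication and NF-kB after reversine, cholesterol and HIF targets, proteasome subunits and DNA replication after BafA1, and DNA replication after MG132. The fatty acid list after BafA1 passed wherever it was tested, but too few of its members had only transcripts of at least 400 nt for a test there.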
